A study of Bacillus atrophaeus with 5 samples.

How the data were processed

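RNA was sequenced from 5 liquid cultures of Bacillus atrophaeus strain UCMB-5137, a spore-forming soil bacterium described by the series title as promoting plant growth. All cultures grew in 1C medium, a rich broth of casein and soya digests with glucose, at 24 °C to an optical density (OD600) of 1, where growth enters stationary phase. The medium of 2 cultures (exudate group) also held 0.25 mg/ml maize root exudate, and 3 cultures without it were the controls. Groups were taken from the condition label of each sample. Replicate numbers come from the sample titles, where unnumbered titles were taken as replicate 1, so the exudate libraries are replicates 1 and 3. Per the labels' protocols, ribosomal RNA was reduced with Ribo-Zero and the cDNA was sequenced on an Illumina MiSeq. The labels call the samples cultures but do not say whether each was grown on its own day, so p-values measure the spread between these samples, which may be partly technical.

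The authors deposited 1 table per library with a whole-number read count for each of 4096 coding sequences, identified by locus tag, per the file headers. The aligner, the counting program, the annotation, the use of strand and the treatment of reads that match several places are not given in the sources used here. Genes with near-identical copies or overlapping neighbours may therefore share reads. All values were whole numbers and were assumed to be counts that had not been normalized. Each deposited count table was read as it stands. In control replicate 1, 76 values are written in quotes with a comma as digit separator and 2 decimals, all of them whole, while its other values and those of the other 4 files are in plain digits. The commas were removed and the values used as counts. These values hold 41.0% of that library's counts.

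The files do not pair the locus tags with gene names, and no annotation was used here. The 32 lists of genes that were fixed by symbol in advance could not be matched to any tag, so the planned gene list tests were not run. For the same reason only 2 tags that rose and 2 that fell are printed, with the 5 most abundant tags. Locus tags are usually numbered along a chromosome, but coordinates were not used here, and a tag's place is given as its position in the tag order, from 1 to 4096.

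Total counts per library were 2273121, 2247647 and 2578625 for control replicates 1 to 3, and 1680111 and 1431690 for exudate replicates 1 and 3. A count of 0 allows up to 3 counts in a library, equal to between 0.611 CPM (control replicate 1) and 2.92 CPM (exudate replicate 3), where CPM is the count relative to the scaled library size described below, or 1.35 CPM over the exudate group. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of libraries differed by more than sampling noise. The chi-square statistic per degree of freedom, over tags with at least 20 counts in a pair, ranged from 13.9 for the exudate pair to 331. All 5 were kept as separate samples, though this statistic cannot tell separate cultures from repeat preparations of 1 culture.

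The comparison used edgeR 4.0.16 in R 4.3.3 on the counts: filterByExpr with its default minimum count of 10, trimmed-mean (TMM) scaling and the quasi-likelihood F test of exudate against control, with no covariate. Tags with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. The filter left 3099 tags and removed 997, which held at most 1.27% of any library's counts. CPM values in the text use the TMM-scaled library sizes. Fitted fold changes of tags with 0 counts in both exudate libraries depend on a prior count, so medians that include such tags are also given with those tags at the bound set by 3 counts over the exudate group. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. On simulated data with the means, dispersions and library sizes of these 5 libraries and 3099 tags, the test recovered 31 of 100 tags changed 4-fold and 86 of 100 changed 16-fold, with 7 false calls among 2801 unchanged tags that were tested. Each tag was simulated independently, without shifts shared by many tags of a library, so this number of false calls may not carry over to the real libraries.

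The tags named in the text were fixed by a rule: among called tags whose exudate libraries both lie beyond all controls, the 2 largest fitted log2 fold changes in each direction, plus the 5 tags with the highest mean share of counts. Runs of neighbouring tags were defined after the values were seen, as at least 3 calls of one direction, each at most 3 positions after the call before it. Alternatives planned before the data were examined were 3 other scalings, removal of the 10 most abundant tags, no filter and a stricter filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), leaving out each library in turn, the replicate number as a block, titles with and without a number as a block, and stricter thresholds. Leaving out the 76 tags with comma-written values, the most abundant tag, or the 3 longest runs was added after the data were seen.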

Results

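The transcriptome of Bacillus atrophaeus UCMB-5137 was measured by RNA sequencing in 3 control cultures and in 2 cultures supplied with maize root exudate, the mixture of compounds that maize roots release. Depth ranged from 1431690 to 2578625 counts per library, and 239 to 852 of the 4096 tags had no count in a library. The 2 exudate libraries resembled each other most closely, with a Pearson correlation of 0.955 across the log2 CPM of the tested tags. Among the controls the correlation was 0.919 for replicates 2 and 3, but 0.847 and 0.863 for replicate 1 with each of them. Control replicate 3 correlated with exudate replicates 1 and 3 at 0.874 and 0.873, higher than with control replicate 1. Genes are not independent replicates, so these correlations only describe the libraries. The first principal component, with 55.5% of the variance, separated exudate from control libraries, and the second, with 27.5%, separated control replicate 1 from the other controls. Control replicate 1 also had the fewest tags at 0, 239 against 537 and 587 in the other controls, and a TMM scaling factor of 2.19 against 0.978 and 0.915.

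The counts were concentrated in few tags, and more so with exudate. The tag cds_PBAT_34950 was the most abundant in all 5 libraries and took 31.4% ± 1.04 of the counts with exudate (SD, n = 2) against 14.6% ± 5.93 in the controls (SD, n = 3). The 10 most abundant tags of each library together took 47.4% ± 0.184 with exudate and 28.0% ± 4.75 in the controls. After TMM scaling cds_PBAT_34950 had a log2 fold change of 1.79 (SE 0.68), with both exudate libraries above all controls, but an adjusted p of 0.124 by edgeR's quasi-likelihood test. Over the alternatives its log2 fold change ranged from 1.10, with library totals only, to 2.46, without control replicate 3. By mean share over all 5 libraries, a rank that need not hold in each library, the next most abundant tags were cds_PBAT_33620, cds_PBAT_33670, cds_PBAT_30010 and cds_PBAT_02070. Their shares with exudate were 3.44%, 2.86%, 2.05% and 1.80%, against 2.28%, 1.25%, 1.23% and 1.23% in the controls. Of these, cds_PBAT_33670 came closest to a call, with a log2 fold change of 2.07 (SE 0.64) and an edgeR adjusted p of 0.0595. The other 3 had log2 fold changes of 1.32, 1.56 and 1.27 and adjusted p of 0.246, 0.171 and 0.263 in the same test. With library totals only, the log2 fold changes of cds_PBAT_33620, cds_PBAT_33670, cds_PBAT_30010 and cds_PBAT_02070 were 0.59, 1.19, 0.73 and 0.54, the lowest over the alternatives, and the highest were 1.59, 2.12, 1.85 and 1.47. Without control replicate 1, all 5 of these tags were called higher, with edgeR adjusted p between 0.00184 and 0.0435. The stricter filter, DESeq2 and the block of numbered against unnumbered titles also called cds_PBAT_34950 and cds_PBAT_33670. Upper-quartile factors also called cds_PBAT_33670, and DESeq2 also called cds_PBAT_30010. No other alternative called any of the 5 tags. Over all alternatives the lowest adjusted p of a tag lay between 1.8e-04 and 0.0435, and the highest between 0.633 and 0.816. In control replicate 1 the counts of all 5 tags are among the 76 comma-written values, so leaving those tags out gives them no value. In control replicates 2 and 3, which have no such values, the shares of all 5 tags were below those in both exudate libraries. The 5 tags were chosen by a mean share that includes the exudate libraries, which favours tags with high shares there.

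**Figure D1:**
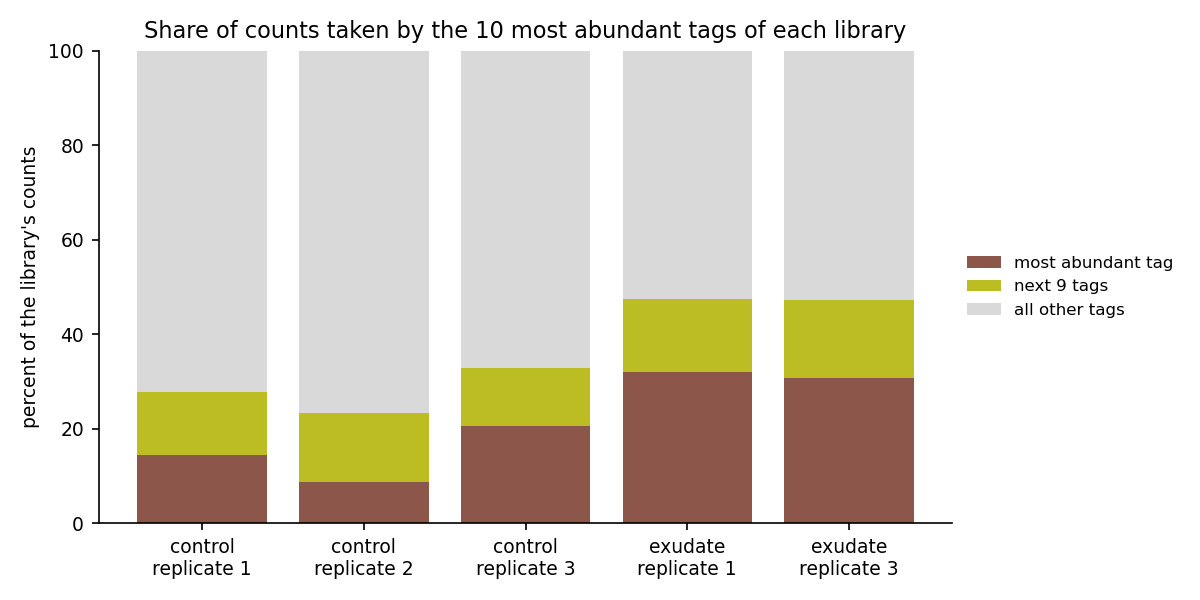
Percent of each library's counts (vertical axis) taken by its most abundant tag, by the next 9 tags and by all other tags, for the 3 control and 2 exudate libraries. The most abundant tag took 32.1% and 30.6% in the exudate libraries and between 8.76% and 20.6% in the controls.

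The design compares cultures with and without root exudate at the same optical density. Of 3099 tags tested, 219 differed, 125 higher and 94 lower with exudate. The 2 directions had different shapes. The 125 higher tags rose by moderate amounts, with a median log2 fold change of 2.35 and a range from 1.69 to 4.89, and 119 of them lay outside any run of neighbouring calls. The 94 lower tags fell further, with a median fitted log2 fold change of -5.28, and 18 of them had no count in either exudate library. With those 18 at their bound the median was -4.60. Both exudate libraries lay beyond all 3 controls for every one of the 219 tags. Over all tested tags the groups did not overlap in 41.5%, where interchangeable libraries would give 20% on average. Tags vary together across libraries, so a single split can lie far from that average, and the difference was not tested.

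Of the tags that rose most, cds_PBAT_04190 went from 27.5 ± 11.5 CPM in the controls (SD, n = 3) to 821 ± 574 CPM with exudate (SD, n = 2). Its log2 fold change was 4.89 (SE 0.71), with an edgeR adjusted p of 8.2e-04. Over the alternatives this log2 fold change ranged from 3.77, without exudate replicate 1, to 5.29, without exudate replicate 3, and was 4.29 without control replicate 2 and 3.81 with library totals only. The tag cds_PBAT_24400 rose from 155 ± 36.0 CPM to 2213 ± 983 CPM, a log2 fold change of 3.84 (SE 0.67) with an edgeR adjusted p of 0.00156. Its range over the alternatives was from 2.85, with library totals only, to 4.07, and the value was 3.18 without exudate replicate 1. The lowest fitted log2 fold changes, a rank that depends on the prior count, were those of cds_PBAT_09110 and cds_PBAT_09200. These tags had 70.8 ± 44.8 and 63.3 ± 37.4 CPM in the controls and 0 counts in both exudate libraries. Set against a floor of 3 counts over the exudate group, which equals 1.35 CPM, they were at least 52.4-fold and at least 46.9-fold lower, each with an edgeR adjusted p of 8.2e-04. Of these 4 tags, limma-voom did not call the pair that fell, with adjusted p of 0.115 and 0.0941; over the alternatives their adjusted p ranged from 4.6e-09 and 5.8e-09 up to these values.

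Of the lower calls, 54.3% came from 3 stretches of neighbouring tags that were almost without reads in the exudate libraries. That share was 20.1% without control replicate 1, where 254 tags were called lower, 85.7% without control replicate 3 and 81.8% without exudate replicate 1 or without exudate replicate 3, and 26.7% with numbered and unnumbered titles as a block, 84.6% with limma-voom and 90.4% at an adjusted p under 0.01. These runs were picked out after the values were seen. They lie at positions 118 to 121, 138 to 157 and 892 to 921 of the tag order and hold 54 tags, of which 51 were tested and 51 were called lower by edgeR, but limma-voom called 11 of these 51. The least changed of them had a log2 fold change of -3.07, and 8 had no count in either exudate library. Their median log2 fold change was -5.63, or -5.46 with those 8 at their bound. With limma-voom the median was -5.56, and all 51 log2 fold changes were negative. The tags were chosen as lower calls on the same counts, so these signs are not separate support. Summed over the run, positions 892 to 921 had 8597 ± 6268 CPM in the controls (SD, n = 3) and 165 ± 16.9 CPM with exudate (SD, n = 2), 52.0-fold lower. Positions 138 to 157 had 5421 ± 4381 CPM against 124 ± 81.1 CPM, 43.9-fold lower. Without control replicate 2 these folds were 32.9 and 24.2, and for positions 138 to 157 the fold was 81.9 without exudate replicate 1. The short run at positions 118 to 121 had 157 ± 144 CPM against 7.32 ± 6.22 CPM, 21.5-fold lower, but 10.5-fold without control replicate 2, 53.9-fold without exudate replicate 1 and 13.4-fold without exudate replicate 3. The level of the 3 runs also differed between the controls. Together they had 4284 CPM in control replicate 1, 25526 in replicate 2 and 12716 in replicate 3, and 346 and 246 CPM in exudate replicates 1 and 3. The lowest control was 12.4 times the highest exudate library for this sum, and 13.5, 9.87 and 3.62 times for the runs from positions 892, 138 and 118. With 3 libraries against 2 there are only 10 splits, so no exact permutation test of such a sum can give a p under 0.05. If the one-sided p is doubled, it cannot lie below 0.2.

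**Figure D2:**
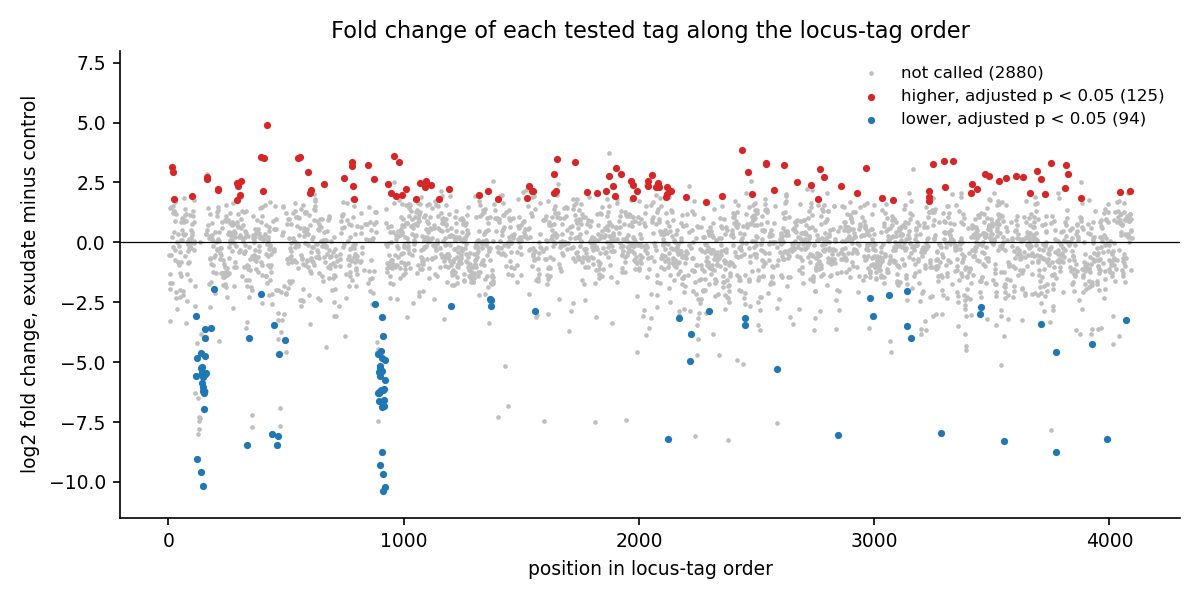
Log2 fold change of exudate over control (vertical axis) for each tested tag against its position in the tag order (horizontal axis); red points are the 125 higher and blue points the 94 lower calls of edgeR's test. Blue points crowd between positions 118 and 157 and between 892 and 921, while red points are spread over the whole order.

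**Figure D3:**
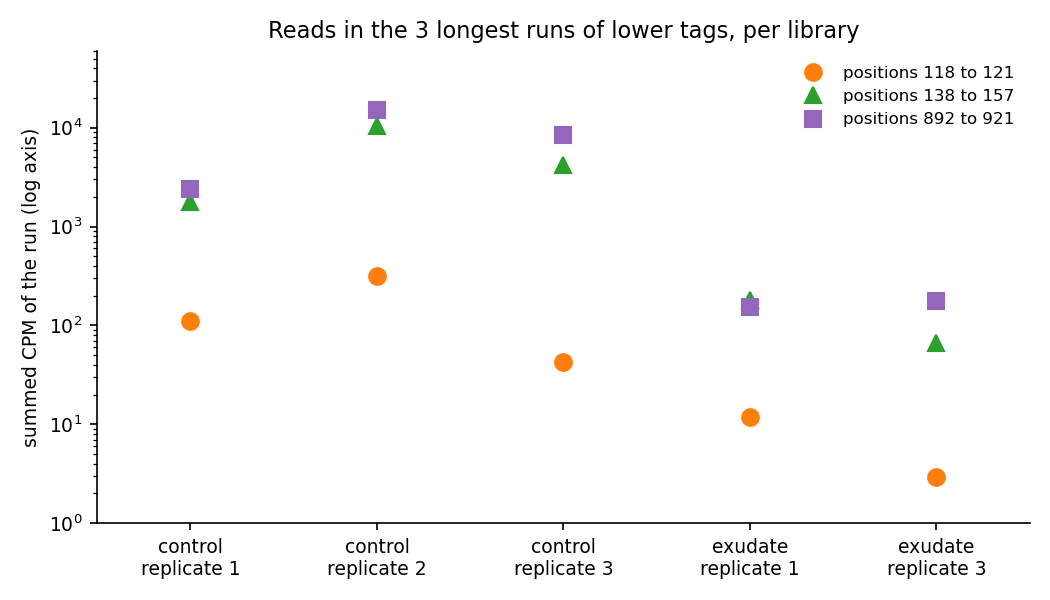
Summed CPM (vertical axis, log scale) of the 3 longest runs of lower tags in each of the 5 libraries, 1 point per run and library. All 3 runs are lower in both exudate libraries than in any control, and the controls differ, with replicate 2 highest.

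Low exudate counts were not limited to the called tags. The 16 positions between the first 2 runs, 122 to 137, held 9 tested tags, of which none was called and 8 had negative log2 fold changes, with adjusted p from 0.0570 to 0.199 by edgeR's test. Of these 9, 6 had no count in either exudate library, and the median fitted log2 fold change was -7.29, or -2.81 with those 6 at their bound. Summed over positions 122 to 137, the level was 111 ± 99.1 CPM in the controls (SD, n = 3) and 9.67 ± 4.21 CPM with exudate (SD, n = 2), 11.5-fold lower. Without control replicate 2 this was 6.09-fold, and the lowest control was 1.54 times the highest exudate library. The 4 tested tags just before the run at 892 to 921, at positions 886 to 891, had log2 fold changes from -4.18 to -7.46 and edgeR adjusted p from 0.0558 to 0.114, and none was called. The 7 tested tags in the 10 positions after that run had a median of -0.14, and the 9 after position 157 a median of 0.53, with 1 of these called lower and 2 called higher. Before position 118 the median of 8 tested tags was -1.09, or -0.60 with tags at 0 at their bound. The nearest 4 of them, at positions 112 to 115, had log2 fold changes from -1.84 to -6.29 and a median of -1.72 with tags at 0 at their bound, and none was called. Another run of lower tags at positions 1369 to 1373 held 3 calls among 5 tested tags and went from 332 ± 145 CPM (SD, n = 3) to 76.1 ± 23.7 CPM (SD, n = 2). The lowest log2 fold change in that run was -2.67. A further stretch, between positions 157 and 892, had only negative log2 fold changes among its tested tags, most of them below -2.67. Some of these tags were called lower, but too far apart to meet the rule for a run. Several had no count in either exudate library, so their fitted values depend on the prior count. The 43 lower tags outside the 3 longest runs had a median log2 fold change of -3.49, or -3.39 with the 10 that had no exudate count at their bound.

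The median log2 fold change of all tested tags was -0.17 with TMM scaling and -1.02 with library totals only, which called 15 higher and 120 lower tags. The count was 474 without control replicate 1, 110 and 70 without control replicates 2 and 3, and 70 and 92 without exudate replicates 1 and 3, while the 3 runs held between 41 and 51 calls in these fits. When the 3 runs were taken out before the test, 69 higher and 16 lower tags were called among the remaining 3048. With the runs kept in the test, 125 higher and 43 lower tags were called outside them.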

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

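Of the alternatives, 3 were added after the results were seen: those that leave out the comma-written tags, the most abundant tag or the 3 longest runs. Under every setting run, none of the 219 called tags that was still tested changed sign. For each of them, and for the 9 named tags, both exudate libraries lay beyond all controls. These settings could therefore hardly reverse a sign, and the unchanged signs are little evidence of stability. Of 149 values for the 9 named tags under the alternatives, 134 stayed on their side of the threshold and 0 reversed; 13 passed it newly, all for the 5 abundant tags, and 2 lost it, both under limma-voom. The calls inside the 3 runs numbered 51 and lay between 41 and 51 under the other settings that kept these tags, except limma-voom, which called 11 of them. The planned gene list alternatives were not run, since no list could be matched. The total, higher and lower counts of 219, 125 and 94 moved to 131, 69 and 62 with upper-quartile factors, to 75, 62 and 13 with limma-voom, and to 95, 43 and 52 at an adjusted p under 0.01. Library totals only gave 135 calls, 15 of them higher. The titles with and without a number as a block gave 362 calls, 191 of them lower. With the 3 longest runs left out, the counts were 85, 69 and 16. The main fit called 125 higher and 43 lower tags outside those runs. DESeq2 called 306 tags and gave no adjusted p for 529. Leaving out 1 library at a time gave totals from 70 to 474, with 15 to 220 higher and 49 to 254 lower calls; with 1 exudate library left, its spread was taken from the controls. The replicate block, which uses the number in the titles, called 195 tags, 82 of them higher, and kept 170 of the 219. Equal numbers were not shown to pair the samples: deviations from the group means correlated by 0.04 for the libraries numbered 1 and by 0.10 for those numbered 3. The cause of these shifts was not tested, except that a stricter threshold can only lower a count. At this depth and spread, with a biological coefficient of variation of 0.537, most 4-fold changes would be missed, since the simulated test recovered 31 of 100.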

Other observations

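The tests of placement, of the 3 runs, of control replicate 1, of the comma-written values and of the splits were chosen after the results were seen, while the other scalings and the fits without single libraries were planned. Calls of one direction lay side by side more often than random placement gives. The lower calls formed 53 side-by-side pairs among the 3099 tested tags, where 10000 random placements gave 2.81 on average and 11 at most (permutation p = 0.0001, the smallest they can give). Without the 3 longest runs, the 43 remaining lower calls still formed 5 pairs against 0.581 by chance (permutation p = 7.0e-04). The higher calls formed 10 pairs against 4.96 by chance (permutation p = 0.026, and 0.026 after adjustment over the 3 tests). Tags that share a transcript in a bacterial operon are not independent, so these p-values describe where the calls lie and not how many separate events there were. The higher calls held 2 runs of 3 calls each, among 5 and 4 tested tags. Positions 2117 to 2121 went from 1907 ± 701 CPM in the controls (SD, n = 3) to 6242 ± 394 CPM with exudate (SD, n = 2), and positions 3231 to 3234 from 98.4 ± 15.9 to 342 ± 22.9 CPM.

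Low exudate counts also occurred outside the 3 longest runs of lower calls. The near absence of reads from these 3 stretches of the tag order in both exudate libraries is the pattern most worth following up. Depth and scaling are argued against: the median log2 fold change of their 51 tested tags was -5.63 or lower under each of 4 scalings. With tags at 0 at their bound it was -5.46 or lower. Whichever control was left out, the median was -5.10 or lower, or -4.86 or lower at that bound. The tags were chosen as calls made with all 3 controls, so this cannot decide whether a single control set the difference. A candidate explanation is that the exudate cultures mostly lacked these stretches of DNA, as after loss of a mobile element, and it stays open: the exudate counts departed from the proportions of 2 controls by a chi-square of 5.81 to 7.85 per degree of freedom, against a 95th percentile of 2.03 to 3.27 for the other control thinned to 662 counts, but 3 controls are too few to bound the spread between cultures. Repression of these tags by the exudate and reads shared with copies elsewhere stay open too, since no DNA was measured and the read matching is not described. Whether the 2 longer runs vary as one unit between control cultures also stays open: with TMM scaling, control replicate 2 exceeded replicate 3 and replicate 3 exceeded replicate 1 in 100% of their tested tags, against 22.4% of those outside the 3 runs and 0% in the shortest run, but with library totals the order held in 28 of 28 tags at positions 892 to 921, in 10 of the 19 (52.6%) at positions 138 to 157 and in 7.55% outside the runs.

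Control replicate 1 stood apart from the other controls, and leaving it out raised the number of calls to 474. Greater depth is argued against, since at an equal total of 1431690 counts it had 257 tags at 0 against 596 and 663 in the other controls. A few dominant tags are argued against as well, since its scaling factor was 1.63 without the 10 most abundant tags, against at most 0.934 in the other libraries. Its 3 runs had 12.4 times the CPM of the higher exudate library. The runs were chosen from calls made with this library among the controls, so they had to lie higher in it. This value therefore cannot decide whether it was an exudate culture under a control label. Carried-over genomic DNA, a different library preparation and a real difference between cultures were not tested and stay open.

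A size cut-off alone does not explain the 76 comma-written values of control replicate 1, since 239 values in plain digits were larger than the smallest of them. Size and format were still related: the largest comma-written value was 325922, and the largest in plain digits was 15410. A common factor of 2 or more on these values is argued against, unless an opposite true difference hid it: the median log2 ratio of control replicate 1 to the mean of controls 2 and 3 was -1.18 for these tags and -1.07 for the 276 other tags with more than 1000 counts, a difference of -0.11 with a 95% bootstrap interval over tags from -0.51 to 0.20. A smaller factor stays open, and tags are not independent replicates. The tags so written differed more between exudate and controls 2 and 3 than the others, with a median absolute log2 difference of 1.39 against 0.61. These sets of tags were not matched for abundance. Leaving them out gave 160 calls, and where these values come from stays open.

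For the comparison as a whole, 1 of the 10 splits of the 5 libraries into groups of 3 and 2, the real one, called 219 tags. The highest of the other splits called 0 by edgeR's quasi-likelihood test, with between 11 and 518 tags at an unadjusted p under 0.05, against 689 for the real split. Every other split mixes exudate and control libraries in a group, which widens the spread within groups if the groups truly differ. Their lack of calls therefore does not show how often chance alone would give calls. A design with 10 splits cannot give a share under 0.05.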
